A study of Mus musculus with 40 samples.

How the data were processed

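Messenger RNA was measured by sequencing in punches of the ventral tegmental area, a midbrain region that holds dopamine neurons, from adult mice. Repeated cross fostering (RCF) is an early-life procedure in which a litter passes to a new adoptive mother each day from postnatal day 1 to 4. The 40 libraries fell into 8 groups of 5 by strain (C57 or DBA), sex and treatment (RCF or control), and each group was read from the labels. The labels speak of mice but give neither the animal nor the litter behind each library, so p-values measure the spread between these libraries, and libraries from one litter could not be identified.

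Per the labels' protocols, RNA was extracted from frozen punches with a Norgen column kit, and libraries were made with the Tecan Universal Plus mRNA-Seq kit, which keeps strand. They were sequenced as single reads of 75 nt on an Illumina instrument. Per the submitters' processing notes, bcl2fastq 2.20, cutadapt 1.11 and FastQC were used, with the GRCm38 and mm10 names of the mouse genome build. The aligner, the counting tool, its strand setting, its treatment of reads that match several places and the annotation release are not given in the sources used here. The values deposited by the authors were whole-number read counts per gene, with no normalization.

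The count table held 55471 genes, of which 42664 had a count in any library. Symbols were matched by versioned Ensembl identifier for 54487 genes and without the version for 657, and 327 stayed without a symbol. Coordinates come from the GENCODE annotation of GRCm38. Total counts ran from 16913124 to 28179071 per library. In every pair of libraries of one group the counts differed by more than sampling noise (chi-square per degree of freedom 5.51 to 141 over 80 pairs, genes with at least 20 summed counts), so no library was counted as a duplicate.

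All 40 libraries entered one model with a mean per group, fitted with edgeR 4.0.16 (robust quasi-likelihood F test, TMM normalization, R 4.3.3), with 32 residual degrees of freedom. Low counts were filtered with filterByExpr over the 8 groups, which left 18441 genes, and TMM factors lay between 0.905 and 1.09. P-values were adjusted by the Benjamini-Hochberg method within a comparison, with a threshold of 0.05, and every adjusted p for a gene is from this test unless another tool is named. The median standard error of a log2 fold change in an RCF comparison was 0.18. Values per gene are CPM scaled by TMM, except where CPM of total counts is written. Mean log2 CPM used a prior count of 2.

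The comparisons were RCF against control in each strain and sex, the mean of those 4 differences, the differences of RCF effects between sexes and between strains, and strain and sex among controls. These designs, the gene lists, the naming rule and most alternatives were fixed before the data were examined. Among genes past the threshold, the 12 with the smallest p in each direction were to be named, leaving out unnamed gene models. Where fewer than 5 passed, the 5 smallest p in each direction were given as values. Th, Slc6a3, Slc18a2, Drd2, Nr3c1, Fkbp5, Crhr1, Bdnf, Oprm1 and Fos were always given. For interactions, strain and sex the 6 smallest p in each direction were taken, with known strain and sex genes. Unnamed gene models past the threshold in the RCF comparisons fall outside that rule and were named after their values were seen.

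Gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Of the lists, 31 had at least 3 tested members. The pituitary hormone list had 0 tested members, and its highest value was 12.4 CPM of total counts. The lists and their means per library were planned, and the tests of those means and of gene length were added later. Marker list means were compared by two-sided exact permutation tests, in which 5 against 5 libraries cannot give a p below 0.00794. Correlations used deviations from group means, with 100000 permutations within groups.

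The share of RNA of the other strain was estimated from genes that differ at least 8-fold between strains, with a mean of at least 2 CPM in the strain where they are higher, as the median over the genes higher in the other strain. A 4-fold choice was added after a simulated mixture left few genes at 8-fold. Sequences of the called gene models were matched to reference transcripts at 95% identity or more over at least 75 nt.

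The gene test was checked on simulated counts of 18234 genes with known changes. It recovered 44.8% to 53.7% of genes changed 1.5-fold, 65.7% to 83.6% of those changed 2-fold and 93.9% to 98.5% of those changed 4-fold, with 3 to 8 false calls among 18000 unchanged genes. The simulated genes varied independently of each other, and these changes were placed only in the more abundant genes. Differences in tissue content between libraries of one group were not simulated, so these rates may not hold for the real libraries. A simulated mixture with 25% RNA of the other strain gave estimates of 25.4% and 24.2% at 8-fold.

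Alternatives were DESeq2 1.42.0, limma voom with quality weights, DESeq2 size factors, other filters and thresholds, the compared libraries alone, the replicate number as a block, 2 surrogate variables (sva 3.50.0), marker list means as covariates, and leaving out each library. A rerun without 4 doubted libraries was added after seeing the data. These had Slc17a7 above 100 CPM of total counts or more than 5% RNA of the other strain. They were C57 male control replicates 1 and 5, C57 female RCF replicate 4 and DBA female control replicate 3.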

Results

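Gene expression in the ventral tegmental area was compared between adult RCF and control mice of the C57 and DBA strains and both sexes, with 5 libraries in each of 8 groups. The question was whether daily changes of foster mother after birth left a difference in adult gene expression, and whether it differed by strain and sex. Total counts per library ran from 22035425 to 23922414 in C57 male RCF and from 22475211 to 24684756 in C57 male controls. In the DBA male controls, depth spread most widely, from 16913124 to 25016924.

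Markers of dopamine neurons differed widely between libraries of one group. Th, which encodes the rate-limiting enzyme of dopamine synthesis, ran from 0.655 to 1603 CPM of total counts over the 40 libraries, and Slc6a3, the dopamine transporter gene, from 0.460 to 2885. Markers of nearby or distant regions also reached high levels in single libraries. Slc17a7, a vesicular glutamate transporter abundant in cortex, ran from 2.85 to 1226 CPM of total counts, Pmch, a lateral hypothalamic neuropeptide gene, from 0.407 to 925, and Hoxb5, a hindbrain and spinal cord gene, from 0 to 30.6. The dopamine neuron list had a mean log2 CPM of 5.38 ± 2.06 in C57 male RCF and 4.49 ± 1.93 in their controls (SD, n = 5 each). In C57 females the means were 6.03 ± 2.60 and 4.84 ± 1.94, in DBA males 3.63 ± 0.60 and 4.10 ± 2.19, and in DBA females 4.57 ± 1.65 and 3.83 ± 1.295. Exact permutation tests gave p = 0.476, 0.429, 0.960 and 0.476. Over 14 marker lists and 4 comparisons, 0 of 56 exact tests passed the threshold after adjustment, 5 had an unadjusted p under 0.05, and the lowest adjusted p was 0.444. The lowest exact p, 0.00794, was the smallest that 5 against 5 libraries can give. A single test could therefore not pass after this adjustment, and 0 of 56 does not show equal marker content.

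**Figure D1:**
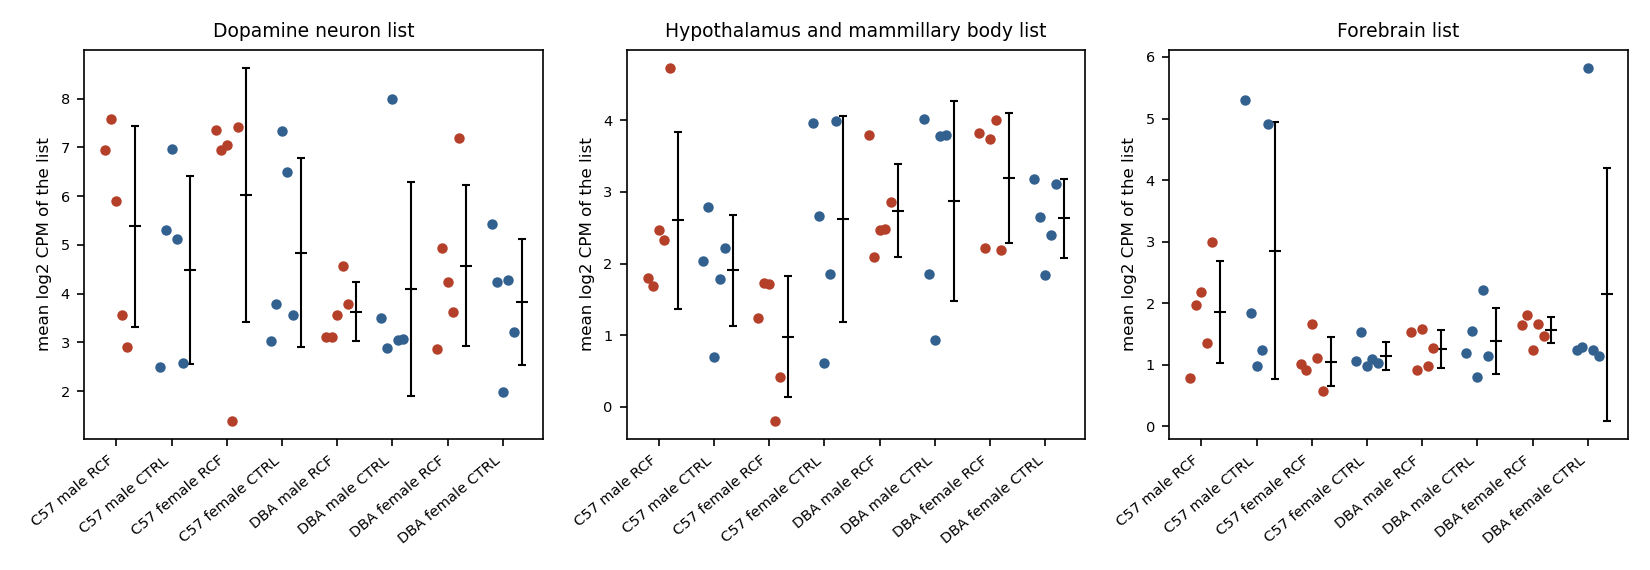
Mean log2 CPM of the dopamine neuron, hypothalamus and mammillary body, and forebrain marker lists (vertical axes) in each library of the 8 groups (horizontal axes). Points are libraries (RCF red, control blue) and bars are the group mean ± SD, n = 5; in C57 female RCF, replicate 4 had a dopamine list mean of 1.39 against 6.95 to 7.42 in the other libraries.

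In C57 males, RCF against control gave 1 gene that rose and 1 that fell. Zfp992 (ENSMUSG00000070605.4), a zinc finger protein gene on chromosome 4 from 146449023 to 146470292, plus strand, GRCm38, fell from 0.783 ± 0.272 CPM in controls to 0.0955 ± 0.0448 in RCF (SD, n = 5 each). Its log2 fold change was -2.96 (SE 0.48, adjusted p = 0.00320, edgeR quasi-likelihood, Benjamini-Hochberg). Zfp992 shares 99.3% of its sequence over 2491 nt with Zfp991, so its count is uncertain where reads could be split between them. The gene model Gm29253 (ENSMUSG00000099519.1, chromosome 1, 75171731 to 75185146, minus strand), named after its values were seen, rose from 0.0344 ± 0.0357 to 1.10 ± 0.263 CPM, with a log2 fold change of 4.79 (SE 0.75, adjusted p = 0.00320). Gm29253 had 16 to 29 counts in the 5 C57 male RCF libraries and 0 to 2 in the other 35, and it overlaps Atg9a and Abcb6 on the same strand.

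Among other genes of C57 males, none passed the threshold. Those with the smallest p and a higher mean in RCF were Rsph14, Lrig2, Zdbf2, Wrb and Rbm34, with log2 fold changes from 0.31 to 2.22 and adjusted p from 0.268 to 0.468. With a lower mean came Eng, an endothelial receptor gene of the TGF-beta family, Eno1b, Cdkn1c, an imprinted cell cycle inhibitor, and Rilpl1, at -0.43, -1.74, -0.95 and -0.37, with adjusted p from 0.276 to 0.362. Without control replicate 5 the value of Eno1b was -0.70. The log2 fold changes were 1.09 (SE 1.47) for Th, 1.42 (SE 2.10) for Slc6a3, 1.33 (SE 1.31) for Slc18a2 and 0.995 (SE 0.80) for Drd2. They were -0.19 for Nr3c1, the glucocorticoid receptor gene, 0.09 for Fkbp5, -0.09 for Crhr1, 0.13 for Bdnf, 0.24 for Oprm1 and 0.66 for Fos. Single libraries decided the dopamine genes, with Th, Slc6a3, Slc18a2 and Drd2 at 0.39, 0.49, 0.40 and 0.41 without RCF replicate 2 and 2.77, 3.39, 2.82 and 1.85 without control replicate 3. Oprm1 was at 0.057 without RCF replicate 5 and 0.51 without control replicate 2, and Nr3c1 ran from -0.31 to -0.099 over the fits that left out 1 library. At an unadjusted p under 0.05 there were 1304 genes, against 922 from chance. Both calls ended without the 4 doubted libraries (adjusted p = 0.207 for Zfp992 and for Gm29253), an alternative chosen after seeing the data, with log2 fold changes of -2.70 and 4.55. That fit lacked control replicates 1 and 5, and whether fewer libraries alone ended the calls was not tested. Zfp992 was also lost with the compared libraries alone (-2.95, adjusted p = 0.162) and by voom (-2.68, adjusted p = 0.552), and Gm29253 without a low-count filter (4.79, adjusted p = 0.148) and with the replicate block (4.84, adjusted p = 0.457). Leaving out control replicate 2 gave 5 genes.

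Camera called 10 lists in C57 males, 3 higher and 7 lower. The forebrain list, 11 tested members, was lower for all 11, with 0 past the threshold over all genes and 7 adjusted over the list alone. Its adjusted p was 0.00696, and adjusted p = 0.861 with an estimated correlation. All 18 tested myelinating oligodendrocyte markers were also lower (adjusted p = 0.00296, and adjusted p = 0.861 with an estimated correlation), with 0 adjusted over the list alone. All 23 dopamine neuron markers were higher (adjusted p = 0.00634, and adjusted p = 0.861 with an estimated correlation), with 0 adjusted over the list alone. Of the other called lists, ribosomal proteins (59 of 83) and imprinted genes (14 of 18) were mostly higher. Microglia (15 of 16), endothelial (14 of 15), meninges (10 of 10), nuclear oxidative phosphorylation (33 of 34) and mitochondrially encoded genes (8 of 9) were mostly lower, each with adjusted p = 0.861 with an estimated correlation. Leaving out 1 library ended each of these calls except the endothelial one. The forebrain call ended without RCF replicate 1 or control replicate 1 or 5 (adjusted p = 0.0853, 0.226 and 0.191), the oligodendrocyte call without RCF replicate 4 or control replicate 4 or 5 (0.116, 0.146 and 0.163) and the dopamine call without RCF replicate 1 or 2 or control replicate 1 or 5 (0.0919, 0.309, 0.211 and 0.191). The ribosomal protein list turned its direction without control replicate 1 (adjusted p = 0.820), and the meninges list had adjusted p = 0.940 without control replicate 3. In the control group, Slc17a7 was at 1122 CPM of total counts in replicate 1 and 480 in replicate 5.

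In C57 females, 1 gene rose and 0 fell. Slc6a5 (ENSMUSG00000039728.15, chromosome 7, 49910146 to 49963856, plus strand), the glycine transporter gene of glycinergic neurons, rose from 0.412 ± 0.307 CPM in controls to 15.0 ± 24.02 in RCF (SD, n = 5 each). Its log2 fold change was 5.16 (SE 0.91, adjusted p = 0.0414, edgeR quasi-likelihood). Slc6a5 was at 56.8 CPM in RCF replicate 4 and 14.4 in replicate 5, and at 1.13 to 1.64 in the other RCF libraries. In replicate 4, Th was at 0.725 CPM and Slc17a7 at 973 CPM of total counts. The forebrain list as a whole was not raised there, with a mean of 1.106 against 0.572 to 1.66 in the other RCF libraries. The highest Hoxb5 value of all libraries, 30.6 CPM of total counts, was also in replicate 4. Whether hindbrain tissue in that punch gave its Slc6a5 value was not tested. Tph2, the serotonin synthesis gene, was at 238 CPM in replicate 5 and 43.7 in replicate 4. Without RCF replicate 4 the log2 fold change of Slc6a5 was 3.46 (adjusted p = 0.325), and the call also ended without control replicate 1, 2, 4 or 5 (log2 fold changes of 4.92, 5.61, 5.28 and 4.98, adjusted p = 0.304, 0.0528, 0.0539 and 0.333). It ended as well without a low-count filter, with the compared libraries alone, with the replicate block, by voom, with marker covariates and without the doubted libraries (log2 fold changes from 2.55 to 5.16, adjusted p from 0.108 to 0.460).

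The next genes in C57 females did not pass by edgeR. Anxa4, Plin4, Tph2 and Ahnak2 had log2 fold changes of 3.01, 2.05, 6.88 and 3.10, each with an adjusted p of 0.0689. The values of Anxa4 and Ahnak2 rested largely on RCF replicate 4, at 0.87 and 0.66 without it. Plin4 was lowered to 1.37 without RCF replicate 2 and Tph2 to 4.54 without RCF replicate 5, their lowest values with 1 library left out. Pcdh20, Rprm, Actn2, Pdzph1 and Kif26a had -1.84, -3.02, -2.14, -3.08 and -0.94, with adjusted p from 0.0689 to 0.103. By DESeq2 these 9 genes passed (adjusted p from 4.94e-05 to 0.0108), and by voom Pcdh20 and Rprm (0.0472 each). Th was at 779 ± 481 CPM in RCF and 345 ± 481 in controls, with a log2 fold change of 1.18 (SE 1.48), and Slc6a3, Slc18a2 and Drd2 had 1.24, 1.24 and 0.78. The values were 0.04 for Nr3c1, 0.32 for Fkbp5 (SE 0.14), 0.82 for Crhr1, -0.73 for Bdnf, -0.25 for Oprm1 and 0.73 for Fos. Bdnf passed by DESeq2 (adjusted p = 0.0463) and by voom (0.0472). Without RCF replicate 4 the value of Crhr1 was 0.12 and that of Fos -0.32. Over the fits that left out 1 library, Oprm1 ran from -0.43 to -0.095 and Fkbp5 from 0.18 to 0.38. Without control replicate 3, Th, Slc6a3, Slc18a2 and Drd2 were at 2.32, 2.59, 2.35 and 1.41. Over the alternatives other than leaving out 1 library, Th ran from 0.11 to 3.49 and Slc6a3 from -0.052 to 6.07. Slc18a2 ran from 0.47 to 2.75 and Drd2 from -0.21 to 1.55 over the same alternatives. At an unadjusted p under 0.05 there were 2301 genes. Leaving out RCF replicate 1, 2, 3, 4 or 5 gave 10, 8, 6, 0 and 4 genes, and control replicate 1, 2, 3, 4 or 5 gave 0, 0, 25, 2 and 0. DESeq2 called 79, voom 85 and the edgeR test without the 4 doubted libraries 0.

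Camera called 14 lists in C57 females, 8 higher and 6 lower. All 17 tested glucocorticoid-responsive genes were higher in RCF, with 0 past the threshold over all genes and 4 adjusted over the list alone. Among them, Plin4, Sgk1, Pdk4 and Errfi1 had log2 fold changes of 2.05, 1.23, 0.69 and 0.40. The list's adjusted p was 1.30e-05, and adjusted p = 0.466 with an estimated correlation. All 18 myelinating oligodendrocyte markers were higher (adjusted p = 4.31e-06, and adjusted p = 0.549 with an estimated correlation), with 0 adjusted over the list alone. Of 83 cytosolic ribosomal protein genes 73 were lower, with 1 adjusted over the list alone (adjusted p = 4.06e-09, and adjusted p = 0.549 with an estimated correlation). In the hypothalamus and mammillary body list, 10 of 13 were lower, with 8 adjusted over the list alone, among them Foxb1, Cartpt, Hdc and Pmch at -2.99, -3.83, -4.47 and -4.84. Its adjusted p was 8.11e-05, and adjusted p = 0.466 with an estimated correlation. Of 24 stress hormone and neuropeptide genes 16 were lower, with 6 adjusted over the list alone (adjusted p = 0.00703, and adjusted p = 0.466 with an estimated correlation), among them Gal, Nts and Npy1r at -2.62, -1.75 and -1.27. Dopamine neuron (22 of 23), synaptic vesicle (18 of 26), microglia (16 of 16), endothelial (13 of 15), meninges (10 of 10) and cytokine genes (8 of 10) were mostly higher, and GABA receptor (14 of 16) and cholinergic genes (6 of 7) mostly lower. Of 27 glutamate genes 17 were lower, with a median of -0.16 and a mean of 0.03, against a lower direction by camera. These lists had adjusted p from 0.466 to 0.659 with an estimated correlation. RCF replicate 4 stood apart from the other RCF libraries in several list means. It was at 2.01 against 3.41 to 3.56 for stress hormone and neuropeptide genes and 5.11 against 5.78 to 6.02 for GABA receptor genes. The dopamine neuron mean was 1.39 against 6.95 to 7.42 and the cholinergic mean -0.60 against 0.80 to 1.59. The hypothalamus and mammillary body mean was -0.20 against 0.41 to 1.73 and the synaptic vesicle mean 8.64 against 8.26 to 8.41. Without replicate 4 the stress hormone and GABA receptor lists stayed past the threshold (adjusted p = 0.0405 and 0.00691). The synaptic vesicle and cholinergic calls ended without it (0.238 and 0.248). The dopamine neuron call ended without RCF replicate 1, 2, 3 or 5 or control replicate 1, 2 or 5 (adjusted p from 0.0522 to 0.158). Calls also ended for endothelial genes without RCF replicate 3 or control replicate 2 (0.119 and 0.0905), meninges without RCF replicate 2 or 3 (0.0722 and 0.124), cytokine genes without RCF replicate 3 (0.0760) and glutamate genes without control replicate 2 (0.0522). The synaptic vesicle call ended as well without RCF replicate 2 or 3 or control replicate 1 or 5 (0.0537 to 0.160) and the cholinergic call without RCF replicate 3 or control replicate 1, 2 or 5 (0.0579 to 0.0801).

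In DBA males, 2 genes rose and 1 fell, all unnamed gene models named after their values were seen. Gm49192 (ENSMUSG00000115000.1), a lincRNA on chromosome 14 from 45944000 to 45991037, minus strand, rose from 5.93 ± 1.81 CPM in controls to 22.0 ± 4.89 in RCF (SD, n = 5 each), a log2 fold change of 1.89 (SE 0.27, adjusted p = 6.61e-04, edgeR quasi-likelihood). Gm48159 (ENSMUSG00000110831.1, chromosome 10, 29534717 to 29614471, plus strand), antisense to Rspo3, rose from 0.145 ± 0.0665 to 1.66 ± 0.561 CPM, a log2 fold change of 3.49 (SE 0.59, adjusted p = 0.00491). Gm43333 (ENSMUSG00000105261.1, chromosome 5, 104070064 to 104072325, minus strand), which overlaps Gm17660 on the same strand, fell from 77.3 ± 132 to 4.70 ± 0.585 CPM, a log2 fold change of -4.03 (SE 0.65, adjusted p = 0.00491). Gm43333 was at 313 CPM in control replicate 4, and without that library its log2 fold change was -1.97 (adjusted p = 0.0304). The call of Gm43333 ended with the compared libraries alone, with the replicate block, by voom and with marker covariates (log2 fold changes from -4.04 to -1.84, adjusted p from 0.0594 to 0.926). That of Gm48159 ended with the replicate block (3.46, adjusted p = 0.329) and by voom (3.52, adjusted p = 0.99995). Without the strand setting of the counting, reads of Gm48159 and Rspo3 cannot be separated with certainty. The same holds for Gm49192 and Gm15218, which overlap on opposite strands.

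Among named genes of DBA males, none passed by edgeR. Tmco4, Slc4a8, a sodium bicarbonate transporter gene, Lrrc71, Lama2 and Zfp125 had log2 fold changes of 0.84, 0.35, 3.07, 0.55 and 3.20, with adjusted p from 0.271 to 0.411. Zxdb, Mx1, an interferon-induced antiviral gene, Klhl30, Nup210l and U2af1, a splicing factor gene, had -0.67, -5.63, -5.18, -3.56 and -0.36, with adjusted p from 0.211 to 0.319. Without RCF replicate 2 the value of Lrrc71 was 0.79, and without control replicate 4 those of Klhl30 and Nup210l were -1.86 and -1.21. By DESeq2, Lrrc71, Zxdb, Mx1, Klhl30 and Nup210l passed (adjusted p from 0.0249 to 0.0493). Th was at 28.2 ± 15.98 CPM in RCF and 358 ± 720 in controls, where replicate 3 alone had 1644 CPM. The log2 fold changes were -3.67 (SE 1.63) for Th, -4.48 (SE 2.39) for Slc6a3, -3.34 for Slc18a2 and -1.50 for Drd2, and without control replicate 3 they were -0.37, 3.24, 0.49 and -0.14. They were 0.17 for Nr3c1, 0.03 for Fkbp5, -0.10 for Crhr1, 0.05 for Bdnf, 0.53 for Oprm1 and 0.46 for Fos, which was 0.063 without RCF replicate 5. Oprm1 was at 0.23 without control replicate 4 and 1.13 without control replicate 1, and Nr3c1 at 0.066 without control replicate 4 and 0.30 without control replicate 2. At an unadjusted p under 0.05 there were 1239 genes, and leaving out control replicate 1 gave 7 genes past the threshold. DESeq2 called 20 and voom 0, with adjusted p by voom of 0.365 for Gm49192 and for Gm43333.

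Camera called 6 lists in DBA males, 3 higher and 3 lower. Of 83 ribosomal protein genes 78 were lower, with a median log2 fold change of -0.09 and 0 adjusted over the list alone (adjusted p = 3.98e-09, and adjusted p = 0.726 with an estimated correlation). In the interferon response list 14 of 19 were higher, with 0 adjusted over the list alone, among them Ifih1 and Oasl2 at 0.72 and 0.76. Its adjusted p was 0.00825, and adjusted p = 0.726 with an estimated correlation. Oligodendrocyte (18 of 18) and meninges genes (10 of 10) were higher and 14 of 16 microglia genes lower, each with adjusted p = 0.726 with an estimated correlation. All 9 mitochondrially encoded genes were lower (adjusted p = 0.0295, and adjusted p = 0.726 with an estimated correlation), with 0 adjusted over the list alone. Control replicate 4, the library with the lowest total counts, stood below the other controls in list means, at 6.68 against 7.55 to 8.45 for oligodendrocyte, 0.94 against 1.89 to 3.25 for meninges and 1.12 against 1.48 to 1.99 for interferon response genes. Without it the oligodendrocyte list turned its direction (adjusted p = 0.795), the meninges call ended (0.180) and the interferon list stayed past the threshold (0.0130). The interferon call ended without RCF replicate 2 (0.138) or control replicate 1 (0.0736), and the mitochondrial call without RCF replicate 2 or 5 or control replicate 2, 3 or 5 (adjusted p from 0.0523 to 0.614). The oligodendrocyte call also ended without RCF replicate 4 or 5 or control replicate 1 (0.389, 0.192 and 0.238), the meninges call without RCF replicate 4 or control replicate 3 or 5 (0.179, 0.160 and 0.0878) and the microglia call without RCF replicate 1 or 2 or control replicate 2, 3 or 5 (0.0524 to 0.179). Of these 6 lists, only the ribosomal protein list stayed past the threshold in each fit that left out 1 library.

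In DBA females, 1 gene rose and 2 fell. Gm2451 (ENSMUSG00000106574.1), a processed pseudogene within Stpg2 on chromosome 3 from 139649379 to 139650377, plus strand, fell from 19.7 ± 1.31 CPM in controls to 0.421 ± 0.0303 in RCF (SD, n = 5 each). Its log2 fold change was -5.53 (SE 0.35, adjusted p = 1.31e-13, edgeR quasi-likelihood). The 5 DBA female controls had 415 to 509 counts of Gm2451 and the other 35 libraries 3 to 16, and 82 other genes have near-identical sequence. Among them is Gapdh, at 99.6% identity over 999 nt, so the count of Gm2451 is uncertain where reads could be split between them. Gm48159 rose from 0.138 ± 0.0859 to 1.42 ± 0.670 CPM, a log2 fold change of 3.32 (SE 0.59, adjusted p = 0.0175). Its counts were 0 to 5 in the 10 DBA controls of both sexes and 19 to 62 in the 10 DBA RCF libraries. Both models were named after their values were seen. Mrpl20 (ENSMUSG00000029066.12, chromosome 4, 155802878 to 155809975, plus strand), a mitochondrial ribosomal protein gene, fell from 46.5 ± 3.11 to 35.6 ± 1.77 CPM, a log2 fold change of -0.38 (SE 0.07, adjusted p = 0.0314). Mrpl20 passed in 1 of the 10 fits that left out a library of these groups, that without control replicate 4, with log2 fold changes from -0.40 to -0.35 and adjusted p from 0.0584 to 0.286 in the others. It was also lost with DESeq2 size factors, without a low-count filter, with the compared libraries alone, with the replicate block, with 2 surrogate variables and without the doubted libraries (log2 fold changes from -0.38 to -0.36, adjusted p from 0.0541 to 0.284). Gm48159 was lost without RCF replicate 5 or control replicate 3, 4 or 5 (log2 fold changes of 3.02, 3.43, 3.27 and 3.01, adjusted p = 0.0765, 0.0602, 0.0523 and 0.112). It was also lost with the compared libraries alone (3.33, adjusted p = 0.121), with the replicate block (3.24, adjusted p = 0.260) and without the doubted libraries (3.44, adjusted p = 0.0579), and 1 gene passed without RCF replicate 5, control replicate 3 or control replicate 5.

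**Figure D2:**
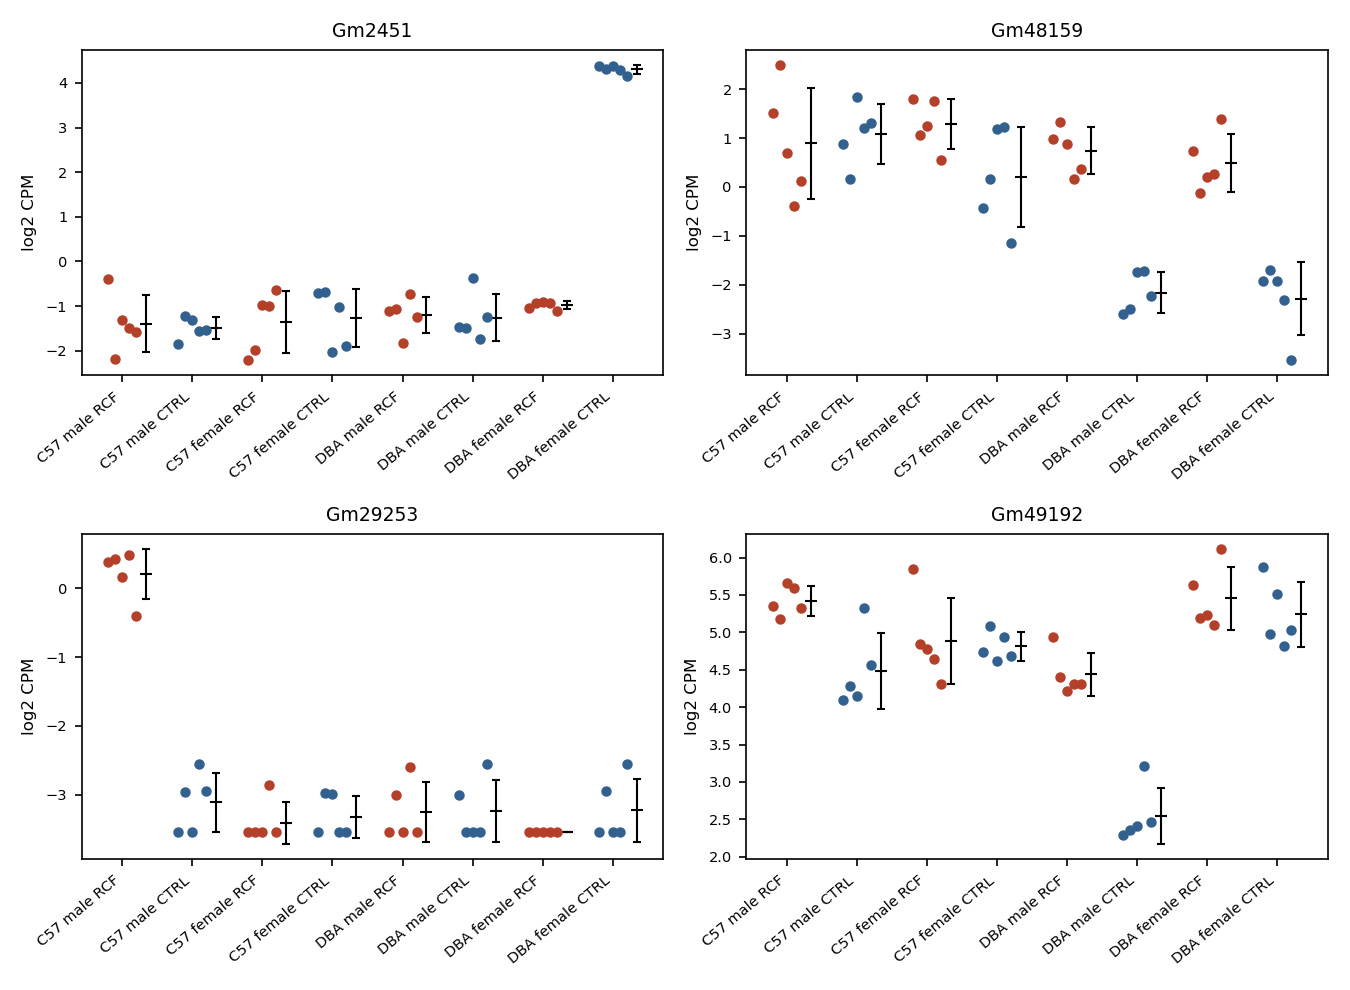
Log2 CPM of the gene models Gm2451, Gm48159, Gm29253 and Gm49192 (vertical axes, log2 scale) in each library of the 8 groups (horizontal axes). Points are libraries (RCF red, control blue) and bars are the group mean ± SD, n = 5. The lowest values of Gm48159 and Gm29253 are libraries with 0 counts raised by the prior count of 2. The Gm2451 counts of the DBA female controls, 415 to 509, lie above the 3 to 16 of all other libraries.

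The next genes in DBA females did not pass by edgeR. Cep350, Usp24, Prrc2c, Kmt2a, a histone methyltransferase gene, and Rere had log2 fold changes of 0.45, 0.32, 0.42, 0.54 and 0.30, with adjusted p from 0.171 to 0.195. Ccdc85b, Rpl5, Ei24 and BC003965 had -0.49, -0.29, -0.26 and -0.34, with adjusted p from 0.0558 to 0.102. These 9 genes passed by DESeq2 (adjusted p from 0.00403 to 0.0320) and by voom (0.00506 to 0.0158). The values were 1.91 (SE 1.51) for Th, 1.72 (SE 2.12) for Slc6a3, 1.62 for Slc18a2 and 0.75 for Drd2, and without RCF replicate 5 they were -0.44, -1.26, -0.25 and -0.00458. Without control replicate 1, Th, Slc6a3 and Slc18a2 were at 2.93, 3.35 and 2.42. They were -0.23 for Nr3c1, -0.43 for Fkbp5 (adjusted p = 0.243), 0.18 for Crhr1, 0.03 for Bdnf, 0.77 for Oprm1 and 0.60 for Fos, which was 0.067 without RCF replicate 4. Without control replicate 3, Nr3c1 was at -0.052 and Crhr1 at 0.078. At an unadjusted p under 0.05 there were 2261 genes, DESeq2 called 47 and voom 492.

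Camera called 12 lists in DBA females, 5 higher and 7 lower. All 34 nuclear oxidative phosphorylation genes were lower, with a median log2 fold change of -0.21, 0 past the threshold over all genes and 4 adjusted over the list alone. Cox8a, Cox6c, Cox6a1 and Uqcrc1, subunits of respiratory complexes, had -0.34, -0.32, -0.35 and -0.27. The list's adjusted p was 7.67e-12, and adjusted p = 0.415 with an estimated correlation. All 9 mitochondrially encoded genes were lower, with 4 adjusted over the list alone (adjusted p = 2.48e-04, and adjusted p = 0.415 with an estimated correlation). All 17 glucocorticoid-responsive genes were lower, with 2, Klf9 and Fkbp5, adjusted over the list alone (adjusted p = 2.72e-04, and adjusted p = 0.415 with an estimated correlation). Of 23 chromatin and DNA methylation enzyme genes 18 were higher, with 5 adjusted over the list alone (adjusted p = 9.09e-05, and adjusted p = 0.415 with an estimated correlation). Dopamine neuron (23 of 23), cholinergic (6 of 7), interferon response (17 of 19) and imprinted genes (16 of 18) were mostly higher. Oligodendrocyte (18 of 18), microglia (15 of 16), ribosomal protein (68 of 83) and circadian clock genes (14 of 16) were mostly lower, and these lists had adjusted p from 0.415 to 0.750 with an estimated correlation. Without control replicate 3 the dopamine, cholinergic, interferon, circadian clock and imprinted calls ended (adjusted p from 0.0692 to 0.521). The dopamine call also ended without RCF replicate 2 or 5 or control replicate 5 (0.0801, 0.668 and 0.0891) and the interferon call without RCF replicate 3 (0.304). The microglia call ended without RCF replicate 1, 3 or 4 or control replicate 5 (0.0734 to 0.0924), the ribosomal protein call without control replicate 2 or 5 (0.0547 and 0.680) and the oligodendrocyte call without RCF replicate 4 (0.0995). The forebrain list mean was 5.83 in control replicate 3 and 1.14 to 1.28 in the other controls.

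Across the 4 comparisons, camera made 42 list calls, of which 0 held with an estimated correlation and 0 with fry. With an estimated correlation, an unadjusted p under 0.05 was seen for 0 lists in C57 males, 2 in C57 females, 0 in DBA males and 1 in DBA females. Of the 556 list members tested, 0 passed the threshold over all genes in any RCF comparison.

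Averaged over strains and sexes, 2 genes rose and 2 fell, all gene models named after their values were seen. Gm48159 rose with a log2 fold change of 1.95 (SE 0.27, adjusted p = 1.05e-04, edgeR quasi-likelihood) and Gm49192 with 0.79 (SE 0.13, adjusted p = 0.00229). Gm2451 fell, at -1.35 (SE 0.18, adjusted p = 1.05e-04) and Gm43333 fell, at -1.97 (SE 0.31, adjusted p = 0.00203). The average of Gm2451 came from DBA females, since its log2 fold changes were 0.26 in C57 males, -0.12 in C57 females and 0.010 in DBA males (adjusted p from 0.899 to 0.997). For Gm48159 the log2 fold change was 3.49 in DBA males and 3.32 in DBA females, and the model was called in neither C57 comparison. Gm49192 and Gm43333 were each called in DBA males alone. At an unadjusted p under 0.05 there were 1282 genes. DESeq2 called 14 and voom 5.

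The RCF effect differed between sexes for 1 gene in each strain. In C57, Zfp992 had a female effect above the male effect by 4.18 on the log2 scale (SE 0.64, adjusted p = 0.00259). This call ended with the compared libraries alone (4.18, adjusted p = 0.211) and by voom (3.76, adjusted p = 0.133). In DBA, Gm2451 had a difference of -5.54 (SE 0.49, adjusted p = 4.70e-09). Between strains the RCF effect differed for Gm2451 in females, at -5.42 (SE 0.50, adjusted p = 1.18e-08). In males 0 genes passed, with 1500 at an unadjusted p under 0.05 and 0 by DESeq2 and by voom. Fold changes of the 4 comparisons were compared over genes, which are not independent replicates. Pearson correlations lay between -0.188 for C57 males and females and 0.219 for C57 males and DBA females, with adjusted p from 0.56 to 0.87 against 100 relabellings of the libraries. Over genes above the median abundance they lay farther from 0 for some pairs, at 0.596 for C57 males and DBA females, -0.314 for DBA males and females and -0.306 for males of both strains, with adjusted p = 0.48 for each.

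Strain gave larger differences among controls, with 1453 genes higher and 1500 lower in DBA. Of these, 580 were unnamed gene models. The processing notes name the same genome build for both strains, and whether reads of both strains were counted equally well was not tested. Hddc3, Wdfy1, Tuba1c, Hmga1b, Scg5 and Alad, a heme synthesis enzyme gene, rose with log2 fold changes of 1.79, 2.05, 3.76, 4.37, 1.31 and 1.58. Cox7a2l, a respiratory supercomplex gene, Fabp5, a fatty acid binding protein gene, Srp9, Nat8f4, Fggy and Rpl29 fell, at -1.79, -1.85, -1.36, -3.61, -7.78 and -1.42. Among these 12 genes, adjusted p ranged from 8.11e-23 for Cox7a2l to 6.16e-16 for Alad. Gpnmb, a transmembrane glycoprotein gene, was at 0.0692 ± 0.0951 CPM in DBA and 1.54 ± 0.550 in C57 (SD, n = 10 each), a log2 fold change of -4.42. Glo1 and Gabra2, a GABA receptor subunit gene, were higher in DBA by 0.91 and 1.52 on the log2 scale.

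Camera called 10 lists for strain, 1 higher and 9 lower in DBA controls. All 5 blood genes fell in DBA controls (adjusted p = 1.16e-05, and adjusted p = 0.195 with an estimated correlation), with 5 adjusted over the list alone. Of 15 endothelial and pericyte markers 10 fell and 0 rose, with 10 adjusted over the list alone (adjusted p = 2.05e-05, and adjusted p = 0.430 with an estimated correlation). Of 16 microglia markers 8 fell and 0 rose, with 8 adjusted over the list alone (adjusted p = 1.27e-04, and adjusted p = 0.633 with an estimated correlation). Of 19 interferon response genes 5 fell and 0 rose, with 8 adjusted over the list alone (adjusted p = 5.30e-04, and adjusted p = 0.430 with an estimated correlation). Of 9 mitochondrially encoded genes 8 fell, with 9 adjusted over the list alone (adjusted p = 2.20e-05, and adjusted p = 0.430 with an estimated correlation). Of 10 meninges genes 5 fell, with 7 adjusted over the list alone (adjusted p = 0.00197, and adjusted p = 0.765 with an estimated correlation). Of 12 heat shock genes 4 fell, with 4 adjusted over the list alone (adjusted p = 0.0462, and adjusted p = 0.430 with an estimated correlation). Of 18 oligodendrocyte markers 1 fell and all were lower, with 1 adjusted over the list alone (adjusted p = 0.00701, and adjusted p = 0.855 with an estimated correlation). Of 83 ribosomal protein genes 9 fell, 1 rose and 49 were lower, with 10 adjusted over the list alone (adjusted p = 0.0269, and adjusted p = 0.855 with an estimated correlation). Of 16 GABA receptor subunit genes 2 rose and 14 were higher, with 3 adjusted over the list alone (adjusted p = 0.0462, and adjusted p = 0.855 with an estimated correlation). By fry, 7 of the lower lists passed, not the oligodendrocyte or ribosomal protein lists. The dopamine neuron list mean over all libraries was 4.03 ± 1.46 in DBA and 5.19 ± 2.06 in C57 (SD, n = 20 each), a difference of -1.15 with permutation p = 0.0525.

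Sex changed 17 genes in controls, of which 7 rose and 10 fell in females. Xist, the RNA that silences an X chromosome, was at 327 ± 49.0 CPM in females and 0.395 ± 0.377 in males (SD, n = 10 each). The X-linked genes Ddx3x, Kdm5c and Eif2s3x rose by log2 fold changes of 0.46, 0.42 and 0.63, and Sdf2l1 by 0.51 (adjusted p = 0.0361). The Y-linked genes Ddx3y, Kdm5d, Eif2s3y, Uty and Uba1y fell, at -11.48, -9.93, -10.12, -9.87 and -5.80, and the autosomal Ccbe1 at -1.87 (adjusted p = 0.00734). The Sdf2l1 call ended without a low-count filter, with the compared libraries alone, by voom and without the doubted libraries (log2 fold changes from 0.40 to 0.51, adjusted p from 0.0730 to 0.492). It also ended in 14 of the 20 fits that left out 1 control library, with log2 fold changes from 0.43 to 0.56 over the 20. The Ccbe1 call ended by voom (-1.61, adjusted p = 0.0681) and without the doubted libraries (-1.55, adjusted p = 0.0590). Camera called 3 lists, all higher in females. Among 12 heat shock genes 11 were higher in females, with 0 past the threshold and 4 adjusted over the list alone. That list's adjusted p was 1.06e-04, with adjusted p = 0.0490 with an estimated correlation. Of 83 ribosomal protein genes 80 were higher, with 7 adjusted over the list alone (adjusted p = 6.14e-16, and adjusted p = 0.937 with an estimated correlation). Of 34 nuclear oxidative phosphorylation genes 33 were higher, with 0 adjusted over the list alone (adjusted p = 1.75e-04, and adjusted p = 0.937 with an estimated correlation). Without DBA female control replicate 3, 31 genes passed.

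The strain of each library was also read from strain-specific expression. C57 male control replicate 5 had an estimated 24.01% of RNA of the other strain from 37 genes higher in DBA. The other 39 libraries, each read from genes higher in the other strain, lay between -1.59% and 0.984%. From 9 genes higher in C57 the estimate for that library was 40.3%, with -18.3% to 20.8% in the other C57 libraries.

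**Figure D3:**
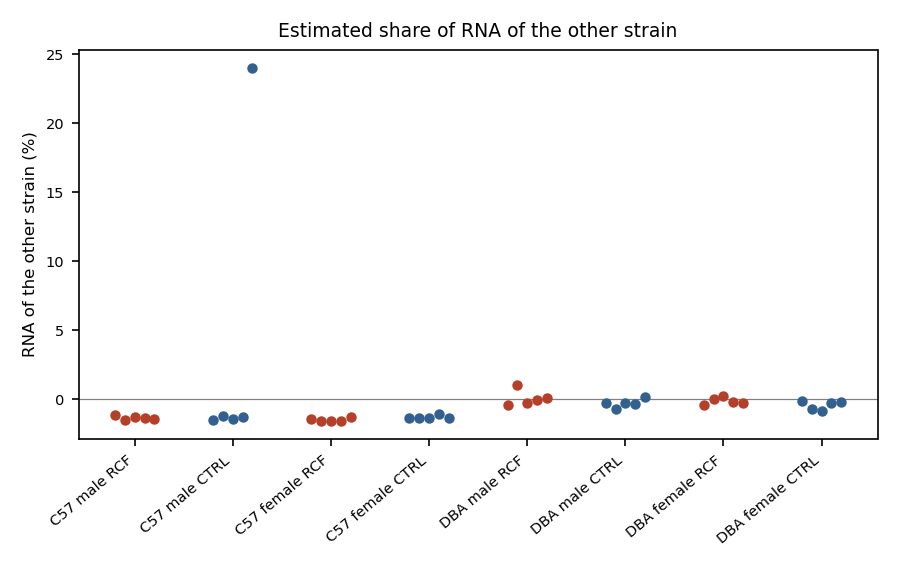
Estimated percent of RNA of the other strain (vertical axis) in each library of the 8 groups (horizontal axis). Points are libraries (RCF red, control blue), and C57 male control replicate 5 stands at 24.01% with all others between -1.59% and 0.984%.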

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

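The tests of neighbouring regions, of an RCF effect on dopamine neurons, of a mislabelled library, of an animal of mixed descent and of reads shared with Gm49192 were chosen only after the results were seen. Dixon's ratio of the gap to the range was taken in 154 groups of 5 values and lay above 0.71 in 24, where chance gives about 7.7.

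Dopamine markers set single libraries apart. In C57 female RCF replicate 4 the ratio was 0.925 for Th, 0.960 for Slc6a3, 0.858 for Slc18a2, 0.949 for Drd2 and 0.922 for the dopamine neuron list mean, with Th at 0.725 CPM against 726 to 1259 in the others. The same library had ratios of 0.801 for Crhr1 and 0.761 for Fos. In DBA male control replicate 3 the ratio was 0.730 for Slc6a3, 0.768 for Drd2, 0.830 for Crhr1 and 0.883 for the dopamine neuron list mean, which was 8.00 against 2.89 to 3.49. Drd2 gave 0.866 in DBA female RCF replicate 5 and 0.718 in DBA female control replicate 3, where Crhr1 gave 0.734 and the forebrain list mean 0.970. The forebrain list mean gave 0.789 in C57 female control replicate 2, the hypothalamus and mammillary body list mean 0.745 in C57 male RCF replicate 5, the raphe list mean 0.766 in C57 female RCF replicate 5, and Bdnf 0.753 in that library.

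The spread of dopamine markers within groups was weighed first. Library depth, tested as a correlation with the dopamine list mean over deviations from group means, gave permutation p = 0.301 (r = 0.179, 40 libraries), against depth as the main cause. Punches that held neighbouring regions in place of dopamine neurons may account for part of the spread. In each library, the hypothalamus, forebrain and raphe list means were taken as deviations from their group means, and the highest deviation was kept. It had r = -0.337 with the deviation of the dopamine list mean (permutation p = 0.0299, adjusted p = 0.0599 over 8 relations, Spearman's rho = -0.344 with p = 0.0289). Without the 2 libraries farthest from the median r was -0.234, so the relation rests partly on them, while forebrain alone had r = -0.470 (adjusted p = 0.00856) and hypothalamus alone r = -0.452 (adjusted p = 0.0350), but raphe, the other list in that measure, r = 0.234 (p = 0.278, adjusted p = 0.344), and GABA neuron markers went with dopamine markers (r = 0.510, adjusted p = 0.0252). An RCF effect on dopamine neurons stays open, since the lowest adjusted p of the 4 exact tests was 0.635 with 5 libraries per group.

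In C57 male control replicate 5 the estimated RNA of the other strain was 24.01% (ratio 0.988), and Zfp992, higher in DBA controls (log2 fold change 1.92, adjusted p = 2.58e-06, edgeR), was at 1.26 CPM there (ratio 0.811). A mislabelled DBA library is excluded by the share of 24.01%, and RNA of a DBA female by Xist at 0.4995 CPM of total counts, where 87.0 would follow from that share. RNA of a DBA animal mixed into the library may account for it, since the share was above 10% on all 17 chromosomes with enough strain markers (15.0% to 39.5%). An animal of mixed descent would carry 0, 1 or 2 DBA copies of each gene. If RNA follows the number of copies, 28 of 37 genes higher in DBA argue against it. They lay above all other C57 libraries but below what 1 of 2 copies would give by the lowest DBA library. These 37 genes also gave the share of 24.01%, and the 9 genes higher in C57 (40.3%) were not in this test, so mixed descent is not excluded. No other explanation was tested. The first choice of 8-fold markers gave 24.01% and the 4-fold choice, added later, 24%, with other libraries from -1.72% to 0.970%, while 9 genes higher in C57 gave 40.3%, against -18.3% to 20.8% in the other C57 libraries, so the size of the share is uncertain.

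Gene models that differed between whole groups were weighed last. A single library is excluded as the cause for the set, since leaving out 1 library ended 1 of 6 calls, that of Gm48159 in DBA females. Reads shared with a near-identical reference transcript are excluded for Gm49192, which 0 other genes match at 95% identity over 75 nt. Gm49192 overlaps Gm15218 on the opposite strand, and reads of that gene are not excluded without the strand setting of the counting. A genome segment that differs between RCF and control animals, and for the other models reads shared with a near-identical gene, cannot be told apart from an RCF effect. Genes within 5 Mb of the called models had an unadjusted p under 0.05 in 9.76% of 410 cases against 8.62% elsewhere (Fisher's exact p = 0.427), but the value set beforehand against a segment was wrong, as a variant in 1 gene need not move its neighbours. Only 1 call, Gm48159 in DBA females, had a matching gene (Rspo3) that moved the opposite way by enough, but the value set beforehand against shared reads was wrong too, as reads with several matches could have been discarded and their handling is not given in the sources used here.

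Other values stood apart without being weighed. The strain share of C57 female control replicate 4 was -1.11% (ratio 0.903). Gm49192 was at 30.6 CPM in DBA male RCF replicate 1 (ratio 0.738) and 9.15 CPM in DBA male control replicate 4 (ratio 0.812). RCF effects differed between sexes by 4.18 for Zfp992 in C57 and -5.54 for Gm2451 in DBA, and between strains by -5.42 for Gm2451 in females, each by an interaction test on the log2 scale.

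Other splits of the libraries were counted, with 100 splits per comparison and the real one included. As many genes as in the real split came in 2 splits for C57 males (real 2, highest other 2), 3 for DBA males (3 and 4), 1 for DBA females (3 and 1), 1 for the average effect (4 and 1), 2 for the sex difference of RCF in DBA (1 and 1), 1 for the strain difference in females (1 and 0) and 1 for strain (2953 and 2710). Chance was unlikely to give these counts, but other splits reached or passed some of them, and the shares were not adjusted over comparisons. Chance remained possible for the counts in C57 females (8 splits, real 1, highest other 39), the sex difference of RCF in C57 (7, 1 and 70) and sex (8, 17 and 334). For sex this concerns the number of genes alone, since Xist and Ddx3y followed the sex labels, with log2 fold changes of 9.72 and -11.48. The strain difference in males had a real count of 0, which every split matches, so the splits could not test it (highest other 2). By voom chance was unlikely for DBA females (2 splits, real 492), though another split called 502 genes. It remained possible by voom for C57 males (12, 1 and 2) and C57 females (10, 85 and 913). In DBA males voom called 0 genes, which every split matches, so the splits could not test it (highest other 3). Splits with 39, 70, 334 or 913 genes called several times the real count, which points to a structure of the samples, and what those splits share was not tested. The split with 2710 exchanged the strain labels of all 10 female controls and of 4 of the 10 male controls, and so kept the strain difference between the females.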

How the results depend on the processing

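The alternative without the 4 doubted libraries was chosen after seeing the data; all others were planned. Counts of genes past the threshold moved as follows, and the cause was not tested. With DESeq2 they were 4 in C57 males, 79 in C57 females, 20 in DBA males, 47 in DBA females, 14 for the average, 129 and 19 for the sex difference of RCF in C57 and DBA, 81 for the strain difference in females and 62 for sex. With voom they were 1, 85, 0 and 492 in the 4 RCF comparisons, 3 for the sex difference in DBA and 270 for the strain difference in females. Without a low-count filter they were 1 in C57 males, 0 in C57 females and 2 for the sex difference in DBA; with CPM above 1 in 5 libraries, 1 in C57 males and 2 for the sex difference in C57. With the compared libraries alone, 1 in C57 males, 0 in C57 females, 1 in DBA females and 0 for the sex difference in C57. Marker covariates gave 0 in C57 females and 40 for sex, and edgeR without robust estimation 2 for the sex difference in C57. At an adjusted p of 0.1 there were 13 in C57 females, 5 in DBA females and 2 for the sex difference in C57, and an absolute log2 fold change of at least 0.5 left 1553 strain genes. Without the doubted libraries, 0 genes passed in C57 males and 0 in C57 females, 2 for the sex difference in DBA and 28 for sex, of which 15 were shared with the 17; in DBA females 3 passed, 1 of them shared. In the fits that called 0, unadjusted p under 0.05 held for 1411 genes in C57 males without the doubted libraries, 605 in DBA males by voom and 2654 for the sex difference in C57 with the compared libraries alone. In C57 females it held for 3382 without a filter, 2168 with the compared libraries alone, 1809 with the replicate block, 1395 with covariates and 1877 without the doubted libraries.

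Replicate numbers did not pair the libraries: same-number correlations ran from -0.274 to 0.128 in C57 males, -0.148 to 0.0837 in C57 females, -0.107 to 0.176 in DBA males and -0.0819 to 0.00214 in DBA females, and 0, 1, 2 and 0 of 5 correlated best with their own number. With the replicate block, 0 genes passed in C57 females, 1 in DBA males, 1 in DBA females, 2 for the sex difference in C57 and 1 for the strain difference in males, Slc6a3 was -0.48 in C57 males and 0.57 in DBA males, and 3 lists were called in DBA males.

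With an estimated correlation, and with fry, 0 lists were called over the 4 RCF comparisons, 0 in C57 males, 0 in C57 females, 0 in DBA males and 0 in DBA females. Log2 fold changes that reversed were none past the threshold. With covariates: Th -0.29, Crhr1 0.00358 and Slc6a3 -0.72 in C57 males, Drd2 -0.16 in C57 females, Slc6a3 1.303 in DBA males, and Th -0.0991, Drd2 -0.0473, Slc6a3 -0.73 and Slc18a2 -0.27 in DBA females. With 2 surrogate variables: Slc6a3 -0.17 in C57 males, Drd2 -0.21 and Slc6a3 -0.0520 in C57 females, Slc6a3 1.49 and Fkbp5 -0.0113 in DBA males, and Th -0.49, Drd2 -0.0946, Slc6a3 -1.77 and Slc18a2 -0.33 in DBA females. With voom: Slc6a3 -0.56 in C57 males, Fos -0.21 and Nr3c1 -0.0234 in C57 females, Slc6a3 0.88 and Crhr1 0.00422 in DBA males, and Slc6a3 -0.71 in DBA females. Without the doubted libraries: Nr3c1 0.0245 in C57 males, Fos -0.32 and Nr3c1 -0.00309 in C57 females, and Bdnf -0.0590 in DBA females. The dopamine neuron list turned with 2 surrogate variables (adjusted p = 0.729 in C57 females and 0.226 in DBA females), as did the correlation of C57 and DBA male effects (0.0433), and Spearman's rho of C57 female and DBA male effects was 0.0387.

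Leaving out each library gave 2 to 5 genes in C57 males (5 without control replicate 2), 0 to 25 in C57 females, 3 to 7 in DBA males (7 without control replicate 1), 1 to 4 in DBA females, 4 to 5 for the average, 1 to 6 and 1 to 1 for the sex difference in C57 and DBA, 0 to 1 and 1 to 1 for the strain difference in males and females, 2546 to 3327 for strain and 13 to 31 for sex (31 without DBA female control replicate 3). For the sex difference in C57 there were 2 without C57 male RCF replicate 2, 3 without C57 male control replicate 1, and 6, 3 and 2 without C57 female RCF replicate 1, 2 and 3. The list calls were 34 to 42 in total, 3 to 10 in C57 males (5, 6 and 3 without RCF replicate 1, RCF replicate 5 and control replicate 5), 8 to 16 in C57 females (8 without RCF replicate 3), 3 to 7 in DBA males (3 without RCF replicate 2, control replicate 3 or control replicate 5) and 7 to 13 in DBA females (7 without control replicate 3). Correlations of effects ran from -0.236 to -0.0590 for C57 males and females, -0.0976 to 0.0353 for males of both strains, 0.0164 to 0.338 for C57 males and DBA females, -0.0671 to 0.101 for C57 females and DBA males, -0.145 to 0.0600 for females of both strains and -0.226 to -0.0717 for DBA males and females. Signs turned for Bdnf (-0.0530 to 0.23 in C57 males, -0.0436 to 0.12 in DBA males, -0.0631 to 0.14 in DBA females), Crhr1 (-0.18 to 0.0137 in C57 males, -0.18 to 0.15 in DBA males), Fkbp5 (-0.0144 to 0.20 in C57 males, -0.0354 to 0.12 in DBA males), Fos (-0.32 to 0.93) and Nr3c1 (-0.00394 to 0.0937) in C57 females, Slc6a3 (-5.55 to 3.24) and Slc18a2 (-3.89 to 0.49) in DBA males, and Th (-0.44 to 2.93), Drd2 (-0.00458 to 1.03), Slc6a3 (-1.26 to 3.35) and Slc18a2 (-0.25 to 2.42) in DBA females. Lists that turned had adjusted p from 7.22e-09 to 0.820 (ribosomal proteins, C57 males) and 0.00210 to 0.795 (oligodendrocyte, DBA males). Gm2451 in DBA females kept its direction and its side of the threshold in every alternative, with log2 fold changes from -5.57 to -5.47. With a median SE of 0.18, changes of 1.5-fold were often missed in simulated counts (44.8% to 53.7% recovered).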

Other observations

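Apart from the edgeR tests, interactions included, the tests in this part were not planned and were added after the data were seen.

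Gm43333, a gene model on chromosome 5 named after its values were seen, passed the threshold in DBA males and in the average over strains and sexes. It was at 2.54 ± 0.367 CPM in C57 male RCF and 5.68 ± 0.986 in their controls, at 3.71 ± 0.898 and 5.38 ± 0.554 in C57 females, and at 7.31 ± 6.38 and 32.6 ± 3.79 in DBA females (SD, n = 5 each). Gm48159, an antisense model named in the same way, was at 2.31 ± 1.99 CPM in C57 male RCF and 2.18 ± 0.907 in their controls, and at 2.48 ± 0.865 and 1.303 ± 0.879 in C57 females, levels of the same order as in DBA RCF libraries. A difference of its RCF effect between strains did not pass in the interaction tests, which by edgeR called 0 genes in males (1500 at an unadjusted p under 0.05) and Gm2451 alone in females.

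Cholinergic markers of the oculomotor and interpeduncular nuclei had a mean log2 CPM of 2.09 ± 0.28 in DBA female RCF and 1.33 ± 0.28 in their controls, with no overlap (exact permutation p = 0.00794, the smallest possible, adjusted p = 0.444 over 56 tests and 0.0317 over the 4 tests of that list). The hypothalamus and mammillary body list mean was 0.98 ± 0.85 in C57 female RCF and 2.62 ± 1.44 in their controls (exact p = 0.0635, adjusted p = 0.508).

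Log2 fold changes were compared with gene length over 9220 genes, which are not independent replicates. Spearman's rho was 0.0182 in C57 males, 0.0720 in C57 females, 0.178 in DBA males and 0.286 in DBA females, and 96, 63, 22 and 22 of 100 relabellings of the libraries gave a value as far from 0 (adjusted p = 0.96, 0.84, 0.44 and 0.44).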
